A study of Mus musculus with 4 samples.

How the data were processed

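Bulk RNA-seq of the small intestine was analysed for 4 libraries from mouse pups under a model of necrotizing enterocolitis (NEC), 2 from Fxr fl/fl pups and 2 from Fxr cko pups. Groups and library numbers were taken from the sample titles and checked against the genotype labels. Per the labels' protocols, Novogene prepared the libraries and sequenced them on a NovaSeq 6000 as paired reads of 150 bp. Reads were then trimmed with fastp and aligned with HISAT2 2.0.5, per the labels' protocols. EdgeR 3.22.5 is named in the submitters' processing notes, without its role. The counting tool, the genome build and the annotation are not given in the sources used here.

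The authors deposited a table of 54532 Ensembl genes with a whole-number count per gene and library, not normalized, per the file headers. The deposited table also holds FPKM (fragments per kilobase of gene length, scaled to the library total) for each library, calculated by the authors. Gene symbols, positions and gene types were taken from the same table. Of its gene identifiers, 99.8% are in GENCODE release 21 for mouse (GRCm38), and 98.3% of those have the same coordinates there, so positions are given as GRCm38. In 105 rows the symbol repeated that of an earlier identifier. For a symbol shared by several identifiers, the identifier with the highest total count was used. FPKM served only as a check: over 10795 genes with enough counts in every library, the median ratio of deposited FPKM to FPKM recalculated from the counts lay between 0.92 and 1.0142.

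Total counts were 17711887 and 17237065 in Fxr fl/fl 1 and 2, and 15861832 and 18546196 in Fxr cko 1 and 3. A floor of 3 counts corresponds to 0.165 to 0.191 CPM (counts scaled to library size), and this floor covers counting error only. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with the current dispersion method, glmQLFTest), with TMM normalization. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 16694 genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by the TMM factors, and errors are SD over the 2 libraries of a group. Fold changes are Fxr cko over Fxr fl/fl on the log2 scale with SE and 95% intervals.

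Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, for lists with 5 or more tested members, adjusted over lists. Each list was also tested with camera and an estimated correlation, and with fry, which asks whether the genes of a list move on balance in a common direction. Within each list, genes were adjusted over the list alone as well as over all tested genes. The 40 lists cover FXR targets, ferroptosis and glutathione genes, type 3 immunity, inflammation, the cell types of the intestinal wall, position along the gut, stress and metabolic programmes, neighbouring tissues, RNA quality and sex-linked genes.

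The groups, the tests, the lists and the rule for naming genes were fixed before the data were examined. Named genes are Nr1h4, up to 12 genes per direction with the largest fold change among those that passed with an average log2 CPM of at least 1 and no overlap between groups (gene models, receptor segments and pseudogenes left out), 15 genes set in advance from FXR, ferroptosis and ILC3 biology, and the 4 members with the lowest p of each list described. Genes named outside this rule are marked as chosen after their values were seen.

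The test was run on simulated data made from the libraries' own means and sizes, 10 simulations with 200 changed genes among 16694. It recovered 4.2% of 2-fold, 42.8% of 4-fold, 83% of 8-fold and 92.8% of 16-fold changes, and 51 of 1165 calls (4.38%) were false. Each simulated gene had the dispersion typical of its expression level. Dispersion that differs between genes of like expression and differences shared by many genes of a library were left out. Recovery in the real libraries may therefore be lower. Alternatives were other scaling factors (RLE, upper quartile), no filter, a filter at a CPM of 1 in all libraries, DESeq2 1.42.0, the edgeR exact test, limma-voom, the legacy quasi-likelihood method, a test against a 1.5-fold change, protein-coding genes alone, the 10 highest genes left out, and leaving out each library. Chosen after the data were seen were fits without chromosomes X and Y, without mitochondrially encoded genes, and with the median of the smooth muscle or proximal position list as a covariate. Other splits of the 4 libraries were also tested.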

Results

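RNA was sequenced from the small intestine of mouse pups under a model of NEC, an inflammatory and necrotic disease of the newborn gut. Fxr fl/fl pups carry a floxed gene for the bile acid receptor FXR, and in Fxr cko pups this gene is deleted, in intestinal epithelial cells by the name used in the design text. Each genotype had 2 libraries, called here Fxr fl/fl 1 and 2 and Fxr cko 1 and 3 after their titles. Total counts ranged from 15861832 to 18546196, and 21861 to 22756 genes had a count. Mitochondrially encoded genes took 15.34% of the counts in Fxr cko 1 and 4.65% to 6.68% in the other libraries. The labels do not state that each library came from a separate pup, so p-values measure the spread between these samples, which may be technical. Naïve pups of both genotypes, named in the design text, were not analysed here.

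The comparison asks what loss of FXR in the gut epithelium changes in pups with NEC, as the series title ties FXR in this disease to ferroptosis of epithelial cells and to failing group 3 innate lymphoid cells (ILC3). Nr1h4, the gene for FXR (ENSMUSG00000047638, chromosome 10, 89454234 to 89533585, minus strand), was lower in both Fxr cko libraries. It had 29.7 and 77.8 CPM in Fxr cko 1 and 3 against 143 and 203 CPM in Fxr fl/fl 1 and 2. The group means were 53.7 ± 34.0 CPM (SD, n = 2) in Fxr cko and 173 ± 42.6 CPM (SD, n = 2) in Fxr fl/fl. The log2 fold change of Nr1h4 was -1.68 (SE 0.49, 95% interval -2.80 to -0.57). Nr1h4 was 19th among 16694 genes by p and did not pass over all genes (edgeR adjusted p = 1). Fxr cko 1 and 3 still held 466 and 1386 Nr1h4 counts, and gene totals do not separate deleted exons from kept exons or epithelium from other cells. With Fxr fl/fl 1 left out Nr1h4 passed (log2 fold change -1.91, edgeR adjusted p = 0.0328), and the fold change was -2.62 without Fxr cko 3 and -1.15 without Fxr cko 1.

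Among genes controlled by FXR, both subunits of the transporter that exports bile acids across the basal side of enterocytes were lower in both Fxr cko libraries. Slc51a had 231 and 253 CPM in Fxr fl/fl 1 and 2 and 93.3 and 88.0 CPM in Fxr cko 1 and 3 (log2 fold change -1.42, SE 0.36). Slc51b had 55.1 and 30.2 against 15.4 and 20.2 CPM (log2 fold change -1.26, SE 0.41). Of the 13 tested members of the list of FXR targets and bile acid genes, 9 lay below 0 and 4 above, with a median log2 fold change of -0.48. Slc51a passed when adjusted over the list alone (edgeR adjusted p = 0.0475), and 0 of the 13 passed over all genes, with 3 at an unadjusted p under 0.05. Abcb11, the bile salt export pump, was at -2.80, carried by 22.02 CPM in Fxr fl/fl 1 against 0.549 in Fxr fl/fl 2 and 1.59 and 1.63 in the Fxr cko libraries. Without Fxr fl/fl 2 Abcb11 passed over all genes (edgeR adjusted p = 0.000123), and without Fxr fl/fl 1 its fold change turned to 1.542. Apoc2, a cofactor of lipoprotein lipase, was at 2.06 with under 3.3 CPM in every library. As a group the list was lower (camera adjusted p = 0.0158), with an adjusted p = 0.936 with an estimated correlation (camera). The call was also lost without the low-count filter (camera adjusted p = 0.167), without Fxr fl/fl 1 (0.0557), without Fxr cko 1 (0.217) and without Fxr cko 3 (0.0687).

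The other FXR-linked genes set in advance varied more between libraries of a genotype than between genotypes. Nr0b2, the corepressor SHP, had 17.2 CPM in Fxr fl/fl 1 but 2.36 in Fxr fl/fl 2, against 4.84 and 5.61 in Fxr cko 1 and 3 (log2 fold change -0.90, SE 0.77). Fgf15, the gut hormone that restrains bile acid synthesis in the liver, had 223 and 729 counts against 179 and 470 (log2 fold change -0.48, SE 0.59). The fold change of Nr0b2 turned to 1.148 without Fxr fl/fl 1, and that of Fgf15 to 0.568 without Fxr fl/fl 2 and 0.003 without Fxr cko 1. Fabp6, the bile acid-binding protein of ileal enterocytes, had 5335 counts in Fxr fl/fl 2 and 0 in each of the other 3 libraries. Slc10a2, the ileal uptake transporter for bile acids, had 41 counts there, 5 in Fxr cko 3 and 0 in the others. Both fell under the expression filter in the fit of all libraries and were not tested there. Without Fxr fl/fl 1 Fabp6 was tested, with a log2 fold change of -15.3 that rests on Fxr fl/fl 2 alone. Where Fabp6 had 0 counts, up to 0.191 CPM is allowed by the floor of 3 counts.

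**Figure D1:**
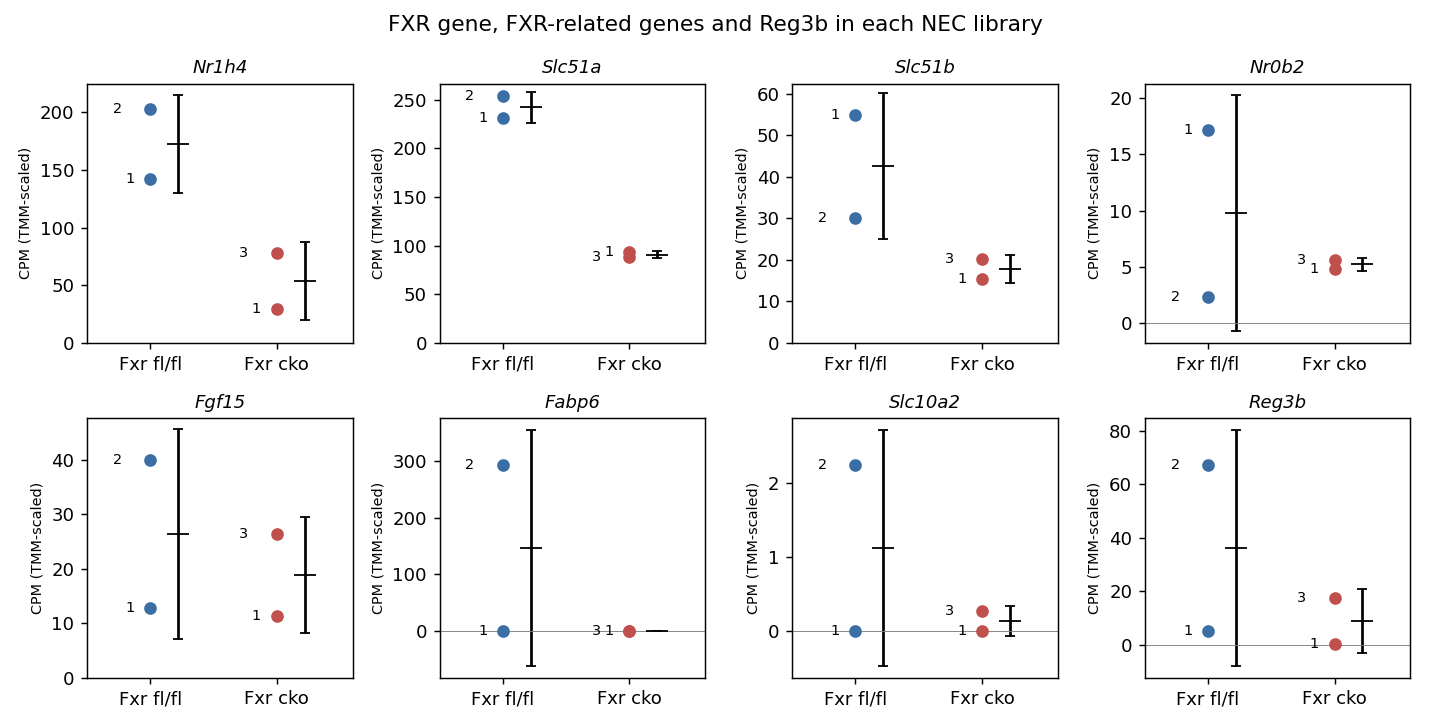
Expression of Nr1h4, 6 FXR-linked genes and Reg3b in CPM scaled by TMM factors, a panel per gene, for Fxr fl/fl (blue) and Fxr cko (red) libraries with the library number beside each point, and mean with SD (n = 2) to the right. Nr1h4, Slc51a and Slc51b lie lower in both Fxr cko libraries, while Fabp6 is counted in Fxr fl/fl 2 alone of these 4 libraries.

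Of 16694 tested genes, 4 were higher and 1 was lower in Fxr cko pups, and all 5 are sex-linked. The 4 higher genes lie on chromosome Y. They are Eif2s3y, a translation initiation factor, Ddx3y, an RNA helicase, Kdm5d, a histone demethylase, and Uty, a relative of histone demethylases. Each had 0 counts in both Fxr fl/fl libraries. With a floor of 3 counts over the Fxr fl/fl group Eif2s3y was at least 976-fold higher, Ddx3y at least 761-fold, Uty at least 462-fold and Kdm5d at least 354-fold higher. Their CPM in Fxr cko 1 and 3 were 96.1 and 69.5 for Eif2s3y and 30.9 and 28.7 for Kdm5d (edgeR adjusted p = 0.00182 and 0.00255). Xist, the noncoding RNA that coats the inactive X chromosome, had 12961 and 9885 counts in Fxr fl/fl 1 and 2 and 22 and 10 in Fxr cko 1 and 3 (log2 fold change -9.36, SE 0.70, edgeR adjusted p = 0.00182). These 5 genes, fixed as the list on the balance of sexes, were higher as a group by camera (adjusted p = 3.16e-20; camera adjusted p = 0.936 with an estimated correlation). They also passed fry (limma, adjusted p = 0.0457), although Xist moved the other way. Sex as read from these genes therefore runs with genotype in all 4 libraries, and no value of this comparison separates them. With a lone Fxr cko library left, without Fxr cko 1 or Fxr cko 3, none of the 5 passed (edgeR adjusted p from 0.199 for Eif2s3y to 0.285 for Xist).

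Outside chromosomes X and Y, edgeR called 0 of 16134 genes, with 91 at an unadjusted p under 0.05 and a smallest adjusted p of 0.133. By other tools, DESeq2 called 2 of them, the edgeR exact test 3 and limma-voom 0. Over all genes 99 had an unadjusted p under 0.05, 49 higher and 50 lower, where 835 would be reached by chance. Only 15.9% of genes had both Fxr cko libraries on the same side of both Fxr fl/fl libraries, where chance gives 33.3%. Across genes the most alike libraries were Fxr fl/fl 1 and Fxr cko 3 (Pearson r = 0.974), with r = 0.933 within Fxr fl/fl and 0.941 within Fxr cko, though genes are not independent replicates. Counts of calls depended on single libraries: without Fxr fl/fl 1 edgeR called 64 genes higher and 25 lower, without Fxr fl/fl 2 it called 27 and 15, and without Fxr cko 1 or Fxr cko 3 it called 0 (41 and 724 at an unadjusted p under 0.05).

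**Figure D2:**
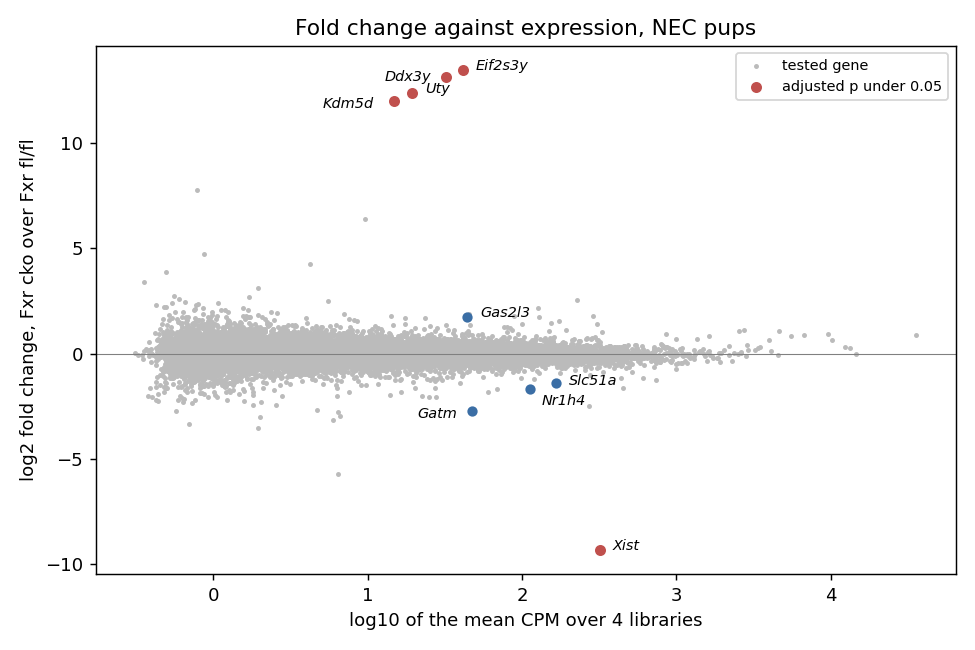
Log2 fold change of Fxr cko over Fxr fl/fl against log10 of the mean CPM over the 4 libraries, a point per tested gene, with the 5 genes past an adjusted p of 0.05 in red and Nr1h4, Slc51a, Gatm and Gas2l3 in blue. The 5 called genes are Xist at -9.36 and 4 Y-linked genes near the top, far from the other genes.

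Genes of ferroptosis, the iron-dependent cell death by lipid peroxidation, did not pass between the genotypes as groups. Gpx4, the enzyme that reduces lipid peroxides, had 355 and 342 CPM in Fxr fl/fl 1 and 2 and 330 and 381 in Fxr cko 1 and 3 (log2 fold change 0.03, 95% interval -0.91 to 0.97; -0.006 without Fxr fl/fl 2 and -0.163 without Fxr cko 3). Acsl4, which loads membranes with polyunsaturated fatty acids, was at 0.27 (SE 0.51; -0.574 without Fxr cko 1). Slc7a11, the cystine importer, had 5, 7, 18 and 4 counts in Fxr fl/fl 1, Fxr fl/fl 2, Fxr cko 1 and Fxr cko 3 and was not tested. Of 21 tested ferroptosis drivers 11 lay above and 10 below 0 (camera adjusted p = 0.701). Among them the oxidase Nox4 was at 0.62, cyclooxygenase Ptgs2 at 0.54, Trp53 at -0.36 and the polyamine enzyme Sat1 at -0.40 (0.173 without Fxr fl/fl 2), and edgeR called 0 of the list's genes over all genes or over the list alone. Of 22 tested suppressors 14 lay above and 8 below 0 (camera adjusted p = 0.303), a list that was higher without Fxr cko 1 (camera adjusted p = 0.0185).

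Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, was highest in the Fxr cko libraries, with 46.0 and 74.3 CPM in Fxr cko 1 and 3 against 26.2 and 32.0 in Fxr fl/fl 1 and 2 (log2 fold change 1.05, SE 0.38). It did not pass when adjusted over the list of ferroptosis suppressors alone (edgeR adjusted p = 0.477). In the same list Acsl3, an activator of monounsaturated fatty acids, was at 0.70, the mitochondrial iron-sulfur protein Cisd1 at 0.41 and the desaturase Scd2 at -1.01, which turned to 1.364 without Fxr fl/fl 2. In the list of glutathione and NRF2 response genes 14 of 23 lay above 0, with a median of 0.06, a mean of -0.09 and a test direction of lower (camera adjusted p = 0.875). Gsta1, a glutathione transferase whose count is uncertain because of near-identical relatives, was at -2.98, G6pdx and Me1, which supply NADPH, at -0.40 and 0.45. Gsta1 turned to 1.89 and Me1 to -0.084 without Fxr fl/fl 2. The list was higher without Fxr cko 1 (camera adjusted p = 0.000323) and lower without Fxr cko 3 (0.0141), and its direction also turned to higher without Fxr fl/fl 2 (0.278). Gsta1 passed over all genes without Fxr fl/fl 1 (edgeR adjusted p = 1.8e-05).

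Genes of ILC3, the lymphocytes that make IL-22 and IL-17 in the gut wall, were mostly at or near the floor. Il22 had 3 counts in Fxr cko 3 and 0 in the other libraries, and Il17a had 0 in all 4. Of the 15 tested genes of ILC3 and type 3 cytokines, 4 lay above and 11 below 0 (camera adjusted p = 0.533). Among them were Kit, a growth factor receptor also carried by pacemaker cells of the gut muscle, at 0.84 (-0.176 without Fxr cko 1), Il1r1 at -0.53, Il18r1 at -1.09 (2.288 without Fxr fl/fl 2) and Ccr6 at 1.02. Without Fxr fl/fl 1 the list was lower (camera adjusted p = 0.00112) and Il18r1 passed (edgeR adjusted p = 0.0396), and without Fxr fl/fl 2 the list's direction turned to higher (camera adjusted p = 0.054).

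Reg3b and Reg3g, lectins of epithelial antimicrobial defence that respond to IL-22, were at -2.02 (SE 1.37) and -0.94 (SE 0.84). Reg3b had 5.02 and 67.3 CPM in Fxr fl/fl 1 and 2 and 0.318 and 17.4 in Fxr cko 1 and 3, so it varied widely within each genotype. Without Fxr fl/fl 1 Reg3b passed (edgeR adjusted p = 3.4e-05), and without Fxr fl/fl 2 Reg3b and Reg3g turned to 0.825 and 0.123. Of 15 tested genes of the IL-22 response, 5 lay above and 10 below 0 (camera adjusted p = 0.449). The calcium-binding protein S100a9 was at 1.99 (SE 0.93), the stress protein Nupr1 at -1.01 (0.062 without Fxr fl/fl 2) and the nitric oxide synthase Nos2 at -0.94. Among 11 tested cytokines and chemokines, 7 above and 4 below 0 (camera adjusted p = 0.839), the alarmin Il1a was at -1.92, the neutrophil attractant Cxcl5 at 1.69, Nfkbiz at 0.61 (-0.309 without Fxr cko 1) and the adhesion molecule Icam1 at -0.38. Neutrophil markers (camera adjusted p = 0.467) held Mmp9 at -1.23 (0.179 without Fxr fl/fl 1), Ltf at -1.49 (1.959 without Fxr fl/fl 2) and Csf3r at -0.60 beside S100a9, and Ltf passed without Fxr fl/fl 1 (edgeR adjusted p = 0.0271). For none of the 4 lists of type 3 immunity, IL-22 response, cytokines and neutrophils did edgeR call a gene over all genes or over the list alone, and Il1a was the member with an unadjusted p under 0.05. In these lists DESeq2, the exact test and limma-voom called 0 genes as well.

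MHC class II genes, with which antigen-presenting cells and some epithelial cells display peptides to T cells, were lower in Fxr cko pups as a group (camera adjusted p = 3.82e-06; camera adjusted p = 0.936 with an estimated correlation, fry adjusted p = 0.864). Of 9 members 8 lay below 0 and 6 were lower in both Fxr cko libraries than in both Fxr fl/fl libraries, with a median log2 fold change of -0.68. H2-Eb1 had 65.4 and 69.7 CPM in Fxr fl/fl 1 and 2 against 33.3 and 42.7 in Fxr cko 1 and 3 (log2 fold change -0.83, SE 0.34). The invariant chain Cd74 had 167 and 155 against 69.7 and 109 CPM (log2 fold change -0.85), and H2-Aa and H2-Ab1 were at -0.74 and -0.55. The call with the preset correlation held without each library in turn (camera adjusted p from 0.00396 to 0.0168). Within the list edgeR called 0 genes over all genes or over the list alone, where the smallest adjusted p was 0.164 and 2 members had an unadjusted p under 0.05.

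Interferon response genes were higher as a group, 16 of 18 lying above 0 with a median log2 fold change of 0.22 (camera adjusted p = 0.000979; camera adjusted p = 0.936 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, had 302 and 126 CPM in Fxr fl/fl 1 and 2 and 403 and 308 in Fxr cko 1 and 3 (log2 fold change 0.73). Ifit3, which has a near-identical copy, was at 0.66, with 13.95 CPM in Fxr fl/fl 2 and 61.7 to 67.2 in the other 3 libraries, and Oasl2 and Usp18 were at 0.65 and 0.62. Ifit3 turned to -0.072 without Fxr fl/fl 2. The low values of Fxr fl/fl 2 carried the group: without that library the list's direction turned to lower (camera adjusted p = 0.178). The call was also lost without Fxr cko 3 (camera adjusted p = 0.135), and Ifit3 passed without Fxr fl/fl 1 (edgeR adjusted p = 0.0328).

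Other immune markers did not pass as groups. Of 16 tested markers of monocytes and macrophages 11 lay below 0 (camera adjusted p = 0.188), with the complement genes C1qa at -0.63, C1qc at -0.60 and C1qb at -0.42, and the scavenger receptor Cd163 at 1.07. T and cytotoxic lymphocyte markers, 11 of 15 below 0, had a camera adjusted p of 0.232 and were lower without Fxr fl/fl 1 (camera adjusted p = 0.00509), and Nkg7, a granule protein, was at -1.37. B and plasma cell markers, 5 above and 5 below 0 with a median of -0.03, a mean of 0.02 and a test direction of higher, had a camera adjusted p of 0.192. That list was lower without Fxr fl/fl 1 (camera adjusted p = 0.000917) and higher without Fxr fl/fl 2 (camera adjusted p = 8.12e-13).

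In the epithelium, markers of goblet cells, which secrete mucus, were lower as a group, with 13 of 14 below 0 and a median log2 fold change of -0.30 (camera adjusted p = 0.0158; camera adjusted p = 0.936 with an estimated correlation). Spdef, the transcription factor of goblet cell maturation, was at -1.03, the protease Klk1 at -1.15 and the mucin-folding protein Agr2 at -0.74. Guca2a, the peptide guanylin, was at -1.26 but had 52.3 and 2019 CPM in Fxr fl/fl 1 and 2, and it passed as higher without Fxr fl/fl 2 (log2 fold change 3.05, edgeR adjusted p = 0.0246). The goblet call was lost without the filter (camera adjusted p = 0.122), without Fxr fl/fl 1 (0.303), without Fxr fl/fl 2 (0.125) and without Fxr cko 1 (0.489).

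Enterocyte markers split evenly, 10 above and 10 below 0 of 20, with a median of 0.00 (camera adjusted p = 0.7). They were higher without Fxr fl/fl 1 (camera adjusted p = 0.000193) or without Fxr cko 1 (0.00434) and lower without Fxr fl/fl 2 (0.0124). Suckling-type enterocyte markers had a camera adjusted p of 0.7, with Lrp2, an endocytic receptor, at -1.28, and adult-type enzymes 0.817. The adult-type list was higher without Fxr fl/fl 1 (camera adjusted p = 0.0379) and lower without Fxr fl/fl 2 (0.016). Enteroendocrine markers, 11 of 15 below 0, had a camera adjusted p of 0.0857, which was 0.0365 without Fxr cko 3, and Reg4, a secreted lectin, was at -1.09. All 5 tested Paneth cell markers lay below 0 (camera adjusted p = 0.232), and that list was lower without Fxr fl/fl 2 (camera adjusted p = 0.000121). Stem cell markers (camera adjusted p = 0.997), tuft cell markers (0.863, median 0.01 and test direction lower) and proliferation genes (0.232) did not pass, although proliferation was lower without Fxr cko 3 (camera adjusted p = 0.0299). Epithelial junction genes had a camera adjusted p of 0.394 and were higher without Fxr cko 1 (camera adjusted p = 0.0184) and lower without Fxr cko 3 (0.00459).

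Cells of the gut wall under the epithelium differed as groups by the preset test, but by different libraries, and Fxr cko 1 also held the highest share of mitochondrial counts (15.34%). Enteric neuron and glia markers were higher, 11 of 12 above 0 with a median of 0.36 (camera adjusted p = 0.00736; camera adjusted p = 0.936 with an estimated correlation), led by the glial filament Gfap. Gfap was at 2.36 (SE 0.88), with 0.228 and 0.275 CPM in Fxr fl/fl and 1.59 and 1.07 in Fxr cko. The synaptic Snap25 was at 0.72, with 43.2 CPM in Fxr cko 1 and 10.04 to 24.4 in the other libraries, and Elavl4 at 0.68. Snap25 and Elavl4 turned to -0.345 and -0.4 without Fxr cko 1. Without Fxr cko 1 the direction of the neuron list turned to lower (camera adjusted p = 0.991), and without Fxr fl/fl 1 its call was lost (camera adjusted p = 0.878). Fibroblast and matrix genes were lower, 11 of 14 below 0 with a median of -0.33 (camera adjusted p = 0.00736; camera adjusted p = 0.936 with an estimated correlation). The growth factor receptor Pdgfrb was at -0.53, fibronectin Fn1 at -0.49, the collagen Col5a1 at -0.46 and Dpt at -0.41. Endothelial markers were lower, 9 of 11 below 0 with a median of -0.39 (camera adjusted p = 0.00736; camera adjusted p = 0.936 with an estimated correlation). Lyve1 of lymphatic vessels was at -0.87, Cdh5 at -0.72, Plvap at -0.63 and Pecam1 at -0.46. The fibroblast call was lost without Fxr fl/fl 1 (camera adjusted p = 0.109), without Fxr fl/fl 2 (0.167) and without the filter (0.0762), and turned to higher without Fxr cko 3 (0.874). The endothelial call turned to higher without Fxr fl/fl 1 (camera adjusted p = 0.853) and was lost without Fxr cko 3 (0.223) and without the filter (0.0762).

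Smooth muscle markers did not pass between genotypes (camera adjusted p = 0.7), and all 10 were higher in Fxr fl/fl 2 and Fxr cko 1 than in Fxr fl/fl 1 and Fxr cko 3. Desmin, Des, had 248 and 550 CPM in Fxr fl/fl 1 and 2 and 446 and 224 in Fxr cko 1 and 3. The smooth muscle list was lower without Fxr fl/fl 1 (camera adjusted p = 0.0301) or without Fxr cko 1 (0.00434). All 13 mitochondrially encoded genes lay above 0 with a median of 1.05 (camera adjusted p = 9.37e-06; camera adjusted p = 0.936 with an estimated correlation). In 0 of them were both Fxr cko libraries above both Fxr fl/fl libraries. The ATP synthase subunit mt-Atp6 was at 2.53, with 708 CPM in Fxr cko 1 and 39.0 to 95.5 in the other libraries, and mt-Co3, mt-Co2 and mt-Nd3 were at 1.55, 1.40 and 1.14. Without Fxr cko 1 mt-Co3 and mt-Nd3 turned to -0.11 and -0.126. Without Fxr cko 1 the direction of the mitochondrial list turned to lower (camera adjusted p = 0.375), and without Fxr fl/fl 1 its call was lost (0.0978). Without Fxr fl/fl 2 mt-Atp6 and mt-Co3 passed over all genes (edgeR adjusted p = 0.00476 and 0.026).

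**Figure D3:**
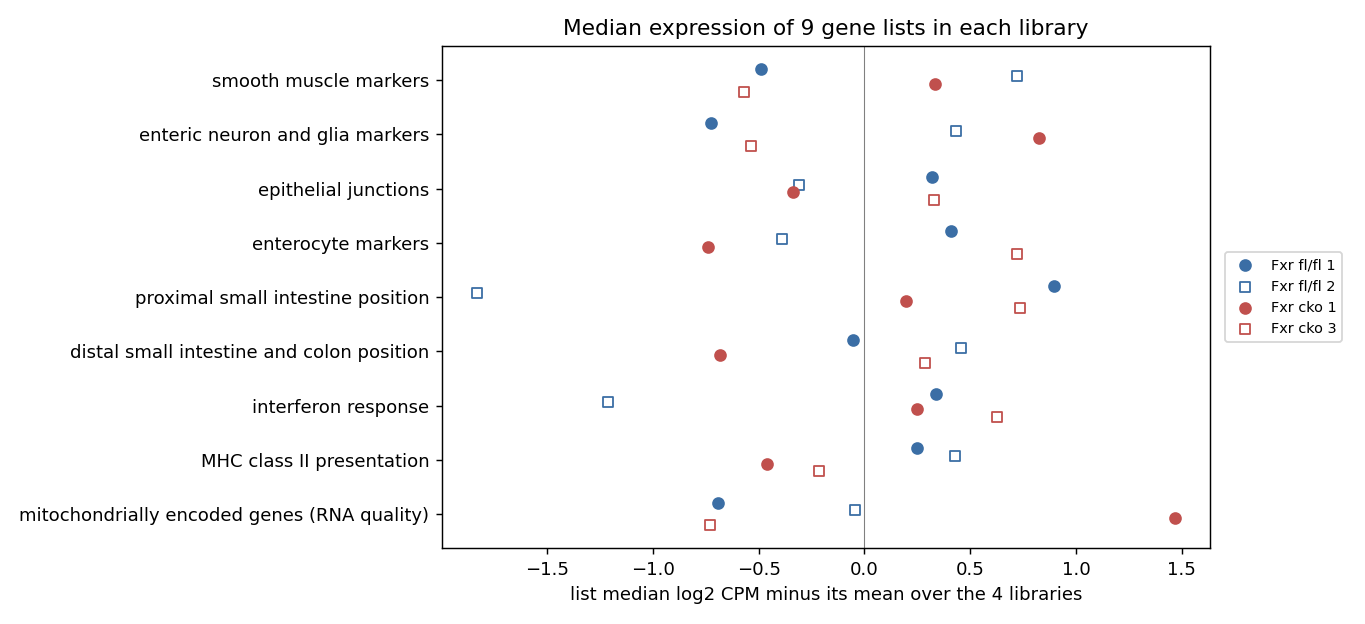
Median log2 CPM of 9 gene lists in each library minus its mean over the 4 libraries, for Fxr fl/fl (blue) and Fxr cko (red), with filled circles for number 1 of each genotype and open squares for Fxr fl/fl 2 and Fxr cko 3. MHC class II lies lower in both Fxr cko libraries, smooth muscle and neuron lists are higher in Fxr fl/fl 2 and Fxr cko 1, and the mitochondrial list is highest in Fxr cko 1.

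Marker genes of position along the intestine were tested as a proximal and a distal list; the labels do not give the segment. The proximal position list had a median of -0.18, a mean of -0.31 and a test direction of higher (camera adjusted p = 0.449), and it was higher without Fxr fl/fl 1 (camera adjusted p = 2.6e-08) and lower without Fxr fl/fl 2 (2.56e-05). Gata4, a transcription factor of the proximal small intestine, had 7.31 CPM in Fxr fl/fl 2 and 61.1 to 133 in the other libraries. Onecut2, a duodenal factor, was at -1.27, with 0.22 CPM there and 7.52 to 42.3 elsewhere. Onecut2 passed as higher without Fxr fl/fl 1 (edgeR adjusted p = 0.00113) and as lower without Fxr fl/fl 2 (0.0291). The distal position list had a camera adjusted p of 0.66. Bcl2l15, in that list, was at -0.50 and passed as higher without Fxr fl/fl 2 (edgeR adjusted p = 0.0292). Of 4 tested liver genes, a list too short for camera, Fga, a fibrinogen chain, passed as lower when adjusted over the list alone (edgeR adjusted p = 0.0211), with 24.4 CPM in Fxr fl/fl 2 and under 0.8 in the others. Fga passed over all genes without Fxr fl/fl 1 (edgeR adjusted p = 4.69e-12). Of 4 tested pancreatic genes, also too few for camera, 2 lay above and 2 below 0. In that list 0 genes passed edgeR over all genes or over the list alone, with 0 at an unadjusted p under 0.05.

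Metabolic and stress programmes did not pass between genotypes. Fatty acid oxidation and PPARA targets had a median of -0.08, a mean of -0.09 and a test direction of higher (camera adjusted p = 0.66), with the pantetheinase Vnn1 at 0.97. That list was higher without Fxr fl/fl 1 (camera adjusted p = 6.35e-06) or without Fxr cko 1 (0.0184) and lower without Fxr fl/fl 2 (0.000349). Cholesterol synthesis genes had a median of -0.04, a mean of -0.03 and a test direction of higher (camera adjusted p = 0.863). Genes of apoptosis, necroptosis and pyroptosis (camera adjusted p = 0.946) were higher without Fxr fl/fl 1 (0.0343) and lower without Fxr fl/fl 2 (0.0423), and the inflammatory caspase Casp4 was at -0.50. Unfolded protein and amino acid stress genes, 14 of 16 above 0, had a camera adjusted p of 0.449 and were higher without Fxr cko 1 (0.00434). Hypoxia and glycolysis genes and immediate early genes each had a camera adjusted p of 0.449, and erythroid genes 0.253.

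Of the 40 lists 38 had enough tested members, and with the preset correlation camera called 4 higher and 5 lower. With an estimated correlation camera called 0 (smallest adjusted p = 0.936, 1 list at an unadjusted p under 0.05), and fry called 1, the sex-linked list, with 2 at an unadjusted p under 0.05. Camera with an estimated correlation gave 0.936 for the sex-linked list as well, where Xist runs against the Y genes. Its misses alone therefore decide nothing on the other lists. The estimates were 0.31 for interferon, 0.35 for MHC class II, 0.55 for neurons and glia and 0.59 for endothelium. They were 0.78 for fibroblasts, 0.97 for mitochondrial and for sex-linked genes, -0.05 for FXR targets and 0 for goblet markers. Where they exceed the preset of 0.01, camera p-values with the preset can be too small. Over the 487 distinct tested genes of the lists other than the sex-linked list, edgeR called 0, with 13 at an unadjusted p under 0.05, and each of these genes had an edgeR adjusted p of 1 over all genes. The 4 higher were Gclc, Gfap, Vnn1 and mt-Atp6, and the 9 lower were Slc51a, Slc51b, Abcb11, Il1a, H2-Eb1, Cd74, Lrp2, Reg4 and Fga. DESeq2, the exact test and limma-voom called 0 of the 487. With the proximal position covariate, chosen after the data were seen, edgeR called 5 of them. These were Abcb11 (log2 fold change -2.85, edgeR adjusted p = 0.0121), Bcl2l15, mt-Atp6, mt-Co3 and mt-Co2. Calls in the lists also changed when an Fxr fl/fl library was left out.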

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

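The fits without chromosomes X and Y, without mitochondrially encoded genes and with a covariate were chosen only after the results were seen; the others were planned. No paired analysis was possible because the groups share only 1 replicate number. Where a library was left out, the lone sample of its group was assumed to vary like the others. The 4 higher genes and 1 lower gene were also the calls with RLE or upper quartile factors, no filter, limma-voom, the legacy method, the 1.5-fold test, the 10 highest genes left out and mitochondrial genes left out. Higher and lower calls were 0 and 0 with the CPM filter in all libraries, which removes the 4 Y genes at 0 in Fxr fl/fl and Xist at 0.561 CPM in Fxr cko 3, and 0 and 0 without chromosomes X and Y, which removes all 5. With protein-coding genes alone 4 were higher and 0 lower, since Xist is noncoding. DESeq2 gave 6 and 2, the exact test 7 and 2, the smooth muscle covariate 6 and 3, and the proximal position covariate 28 and 7; the cause was not tested. Leaving out a library gave 0 to 64 higher and 0 to 25 lower genes, and the log2 fold change of Nr1h4 from -2.62 to -1.15, negative throughout; the cause was not tested.

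The 9 lists past camera became 0 with an estimated correlation and 1 with fry, which use the spread within lists in place of a preset value. Camera called 9 lists with a prior count of 0.5 or RLE factors, 6 with no filter, and 9 to 13 with a library left out. Direction turned in some lists when a library was left out, with camera adjusted p over the 4 libraries from 0.000323 to 0.278 for glutathione and NRF2, 8.12e-13 to 0.787 for B and plasma cells, 0.000193 to 0.194 for enterocytes, 0.016 to 0.217 for adult-type enzymes, 0.00459 to 0.882 for junctions, 5.71e-08 to 0.874 for fibroblasts, 0.00011 to 0.853 for endothelium, 0.000154 to 0.991 for neurons and glia, 2.6e-08 to 0.927 for proximal position, 6.35e-06 to 0.375 for fatty acid oxidation, 0.0343 to 0.361 for apoptosis, 1.27e-11 to 0.178 for interferon and 5.26e-11 to 0.375 for mitochondrial genes. Log2 fold changes ran from -2.31 to 3.05 for Guca2a, -5.82 to 3.12 for Afp, -2.28 to 5.28 for Onecut2 and -2.04 to 5.40 for Bcl2l15, which was 4.005 with the proximal position covariate; the cause was not tested. Of 2919 values of 165 named genes other than Nr1h4 under 18 settings, 2624 kept direction and side of the threshold, within 1 SE where the gene did not pass, 262 moved further or changed sign without passing, 18 newly passed, 10 no longer passed and 5 reversed with a pass. Sign changed in 144 values of 77 genes, 139 of them without a pass. Of the list tests 235 kept direction and side, 42 turned without passing in either setting, 13 turned with a pass, 19 newly passed and 33 no longer passed. With 2 libraries a group, simulated 2-fold changes were recovered in 4.2% of genes, so a missed threshold does not show equal expression.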

Other observations

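The tests of explanations here, the fits with a covariate and the fit without mitochondrial genes were chosen after the data were seen. The bounds for leaving out mitochondrial genes and for thinning to equal depth were set before those 2 tests were run. The lists on tissue layers and gut position were fixed before the data were examined, but which of them to test, and the bounds, were chosen after their values had been seen.

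Gatm (chromosome 2, 122594467 to 122611303), the enzyme that starts creatine synthesis, had the smallest adjusted p outside chromosomes X and Y and was chosen, like all genes of this paragraph, after its values were seen. It had 86.0 and 77.8 CPM in Fxr fl/fl 1 and 2 and 10.4 and 14.4 CPM in Fxr cko 1 and 3 (log2 fold change -2.72, SE 0.37, edgeR adjusted p = 0.133). Gatm passed by DESeq2 (adjusted p = 1.28e-06), by the edgeR exact test (adjusted p = 5.38e-06) and with the smooth muscle or proximal position covariate (edgeR adjusted p = 0.00303 and 3.61e-06). Among the settings where Gatm did not pass were limma-voom (adjusted p = 0.21), no filter (edgeR adjusted p = 0.587) and the CPM filter (0.632). Others were the fit without chromosomes X and Y (edgeR adjusted p = 0.908), RLE factors (0.144) and the legacy method (0.141). Its log2 fold change was -2.64 without Fxr fl/fl 1, -2.8 without Fxr fl/fl 2, -2.51 without Fxr cko 1 and -3.06 without Fxr cko 3. Gm1821, a transcribed pseudogene whose reads are uncertain because of near-identical copies and that was at 1.88, passed by DESeq2 (adjusted p = 0.0259) and the exact test (edgeR adjusted p = 0.0165) but not by the quasi-likelihood test (edgeR adjusted p = 0.83). Gm45774, an antisense gene model whose reads cannot be told from its partner's without strand, passed by the exact test (edgeR adjusted p = 5.14e-05) but not by DESeq2 (adjusted p = 1) or the quasi-likelihood test (edgeR adjusted p = 0.652). It also passed without Fxr fl/fl 1 (edgeR adjusted p = 4.28e-06), without Fxr fl/fl 2 (1.27e-09) and with the smooth muscle or proximal position covariate (9.04e-06 and 3.5e-16). Gas2l3, a cytoskeletal linker gene, lies 10.3 kb from Nr1h4 on chromosome 10 (89408823 to 89443967), on the minus strand like Nr1h4. It had 13.0 and 27.4 CPM in Fxr fl/fl 1 and 2 and 87.9 and 48.5 in Fxr cko 1 and 3 (log2 fold change 1.76, SE 0.47). It was the only one of 14 tested neighbours within 1 Mb with an unadjusted p under 0.05 and did not pass over all genes (edgeR adjusted p = 1). Gas2l3 passed without Fxr fl/fl 2 (edgeR adjusted p = 0.0271) and with the proximal position covariate (0.00365).

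Several other genes, also chosen after their values were seen, lay on the same side in both Fxr cko libraries without passing over all genes when the 4 libraries were fitted without a covariate (edgeR adjusted p = 1 for each). Sprr2a1 and Sprr2a2, epithelial barrier genes with near-identical copies between which reads are uncertain, were at 1.75 and 1.78, and passed without Fxr fl/fl 2 (edgeR adjusted p = 0.00381 and 7.22e-05) and with the proximal position covariate (0.000429 and 9.38e-06). Bmp4, a growth factor of the mesenchyme under the epithelium, had 47.7 and 47.4 CPM in Fxr fl/fl 1 and 2 and 22.7 and 26.03 in Fxr cko 1 and 3. Ccl11, the eosinophil attractant eotaxin, was at -1.85 and passed without Fxr fl/fl 2 (edgeR adjusted p = 0.0174) and with the proximal position covariate (0.0155). The imprinted noncoding RNA H19 was at -1.65, -2.22 without Fxr fl/fl 1 and -0.69 without Fxr fl/fl 2, and had 1014 CPM in Fxr fl/fl 2 against 197 to 348 in the other libraries.

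All 5 genes that passed between the genotypes are sex-linked. Pups of different sex in the 2 groups are a candidate explanation, since all 5 lie on X or Y and the 4 listed Y genes had 0 counts in both Fxr fl/fl libraries. Chromosome Y had 125 and 552 counts in Fxr fl/fl 1 and 2, of which 118 and 544 were from Gm47283. In Fxr cko 1 and 3 this Y gene model, named after its values were seen, held 892 and 149 of 4797 and 3589 counts. Libraries exchanged between the groups are argued against by Nr1h4, whose lowest Fxr fl/fl CPM was 1.83 times its highest Fxr cko CPM, where an exchange would bring the ratio under 1. Whether sex also sets differences outside X and Y, where 91 genes had an unadjusted p under 0.05, cannot be told apart from FXR deletion, because no library pairs the other sex with a genotype. Both stay open for Slc51a and the MHC class II genes.

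The libraries divide across the genotypes: 49.8% of tested genes had Fxr fl/fl 2 and Fxr cko 1 on the same side of Fxr fl/fl 1 and Fxr cko 3. This is the largest share of the 3 possible splits, picked after the shares were seen (15.9% for the genotypes and 34.2% for the remaining split), so the 33.3% that chance gives a split fixed in advance is no bound for it. Dilution by mitochondrial transcripts, which would lower all other genes alike, is argued against as the whole cause: scaled by library totals alone, 30.1% of the other genes were higher in Fxr fl/fl 2 and Fxr cko 1 and 20% lower. Leaving mitochondrial genes out before normalization gave 49.7%, which decides nothing, since TMM factors had already scaled for such a share. Depth is argued against, since 50.1% separated after thinning every library to 15861832 counts. RNA quality stays open: mitochondrial genes took 6.68% and 15.34% of the counts in Fxr fl/fl 2 and Fxr cko 1 against 4.76% and 4.65% in Fxr fl/fl 1 and Fxr cko 3, and ribosomal RNA genes, mitochondrial ones included, 0.329% and 0.475% against 0.146% and 0.257%. Different shares of muscle and nerve layers in the tissue pieces may contribute: 100% of 10 smooth muscle genes and 75% of 12 neuron and glia genes were higher in Fxr fl/fl 2 and Fxr cko 1, against 26% of all genes. In the same libraries 68.8% of 16 epithelial junction genes were lower, against 23.9% of all genes, and of 38 list medians 6 were higher, 12 lower and 20 not separated. Disease severity in each pup, which the labels do not give, was not tested and stays open.

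Fabp6 had 5335 counts in Fxr fl/fl 2 and 0 in the other 3 libraries. FXR deletion alone is argued against for Fabp6 by the 0 counts in Fxr fl/fl 1. Whether Fxr fl/fl 2 held more absorptive cells was not decided. Of 20 enterocyte markers 1 was highest and 11 were lowest there, but the list holds Fabp1, high in the proximal gut, so position could lower such markers. A piece from further down the small intestine is a candidate explanation: 5 of 6 tested proximal genes, Gata4 and Onecut2 among them, were lowest in Fxr fl/fl 2, and 4 of 6 tested distal genes, such as Muc3 at 160 CPM against 28.4 to 107, were highest there, while the proximal gene Ihh was lowest in Fxr cko 1 and the distal gene Slc26a3 was lowest in Fxr fl/fl 2. Lactase, Lct, and Fabp1, both high in the proximal gut and looked at after their values were seen, were also lowest in that library, at 157 and 18.1 CPM. FXR deletion may still matter for Fabp6 where the ileum is sampled in both genotypes, which these 4 libraries do not test.

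The 4 libraries can be split into equal groups in 3 ways, too few for a share under 0.05. The genotypes gave 9 lists past camera and the highest other split gave 15, so 3 of 3 splits gave as many. The split of Fxr fl/fl 1 and Fxr cko 3 from the other libraries had 2695 genes at an unadjusted edgeR p under 0.05 against 99 for the genotypes. It had 0 genes past the adjusted threshold, against 5 for the genotypes, and was singled out after the 3 splits were seen. Genes are not independent, so these counts alone do not show a structure of the samples.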
